A study of Mus musculus with 12 samples.

How the data were processed

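The series holds gene expression arrays of natural killer (NK) cells from mice with (wild type) or without (knockout) the microRNA miR-142. Per the labels, C57BL6 mice of 7 to 10 weeks, matched for age and sex, were used, and CD3-negative NK1.1-positive cells were sorted from spleen and bone marrow. RNA was extracted with Trizol, amplified with a NuGEN Ovation PicoSL kit and hybridised as biotinylated cDNA to Affymetrix arrays, per the labels' protocols. There were 12 arrays in 4 groups of 3 (wild type spleen, knockout spleen, wild type bone marrow, knockout bone marrow), and the labels call the arrays of a group biological replicates.

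The deposited values are log2 signals per probe set. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, which corrects the background, normalizes quantiles over arrays and summarises probes. The versions, the annotation and the genome build are not given in the sources used here. The array medians lay between 5.75 and 5.87 and the upper quartiles between 7.24 and 7.42, and the main fit applied no further normalization. Wild type bone marrow arrays 1, 2 and 3 had the lowest lower quartiles (4.59, 4.60 and 4.55) and the highest upper quartiles (7.41, 7.40 and 7.42). Scaling the arrays again moved the balance of higher and lower genes in bone marrow, over both tissues and between tissues in wild type, as given below.

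The table held 35556 probe sets. The platform annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 12146, and genes were named only from probe sets with 1 symbol. Of those, 21698 were found by gene identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 needed a new symbol. That table was used for names and for which genes neighbour each other, and none of its coordinates is printed. The probe set with the highest mean over all arrays was kept for each of 19938 symbols. Genes with a mean above the 40th percentile, 5.49 on the log2 scale, were tested, which left 11963. Array intensities carry no read depth, so the number of arrays limits the precision.

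A linear model with a mean for each of the 4 groups was fitted in limma 3.58.1 (R 4.3.3), with moderated variances (7 residual and 4.74 prior degrees of freedom). The array numbers in the labels fall into 2 runs, of 7 and 5 arrays. The second run held wild type spleen 3, knockout spleen 1 and 2, and wild type bone marrow 2 and 3, and all knockout bone marrow arrays were in the first. The run was therefore a covariate of the main fit, and was left out where each tissue was fitted alone. Its own effect passed for 0 genes in limma after Benjamini-Hochberg adjustment, with 546 genes at an unadjusted p under 0.05 where 598 would come from chance. Comparisons were knockout against wild type in spleen, in bone marrow and over both, the difference between these effects (the interaction), and bone marrow against spleen within each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and differences are given as log2 ± standard error. The p-values of genes and lists are two-sided.

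Before the data were examined, 30 gene lists of pathways, NK cell programmes and markers of other cell types were fixed, together with the genes within 5 Mb of Mir142. The 27 lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. List tests of the interaction and of the tissue comparisons were added after seeing the data. Counts of changed members are given over all tested genes and adjusted over the list alone.

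Genes were named by a rule fixed before the data were examined. It took Mir142, the 10 largest rises and falls among called genes whose 3 arrays of 1 group all lay on 1 side of the other group, and 2 to 4 members of each list. It also took Itgav, Socs1, Tgfbr1, Tgfbr2, Il2rb, Itga1, Itgam, Cd27, Klrg1, Gzmb, Prf1, Ifng, Bcl2, Mcl1, Eomes, Tbx21 and Kit. Where fewer than 5 genes passed, the 5 with the smallest p were named, and predicted and olfactory or vomeronasal receptor entries were not.

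The steps were tested on simulated data of 11963 genes with 200 changed, in 10 simulations. A log2 change of 1 was recovered for 95.7% of changed genes in the spleen comparison, 91.5% in bone marrow, 99.4% over both, 55.1% in the interaction, 96.9% between tissues in wild type and 92.1% in knockout. A change of 0.5 was recovered for 33.9%, 22.5%, 82.7%, 3.28%, 28.7% and 21.0%, in the same order. False calls made up 4.42% to 5.29% of all calls. A list of 20 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 10 of 10 simulations of each knockout comparison. That threshold is looser than the adjusted one used for the real lists. The simulated genes were drawn independently, so the result does not show how camera performs where genes of a list are correlated.

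Alternatives left out the run covariate, added the replicate number as a block, changed the filter, scaled the arrays again, changed the variance model, averaged probe sets, fitted each tissue alone and left out each array in turn. Alternatives chosen after seeing the data left out wild type bone marrow arrays 1 and 2 or added the level of granulocyte markers as a covariate. Tests of genes with miR-142 binding sites were planned and not run, since no 3' untranslated region sequence was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.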

Results

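NK cells of wild type and miR-142 knockout mice were profiled in spleen and bone marrow, with 3 arrays in each of 4 groups, to find genes whose expression differed and that might contribute to the knockout phenotype. Mir142 itself was measured first. Its log2 signal was 6.77, 7.17 and 7.58 in the wild type spleen arrays and 7.10, 8.25 and 7.14 in wild type bone marrow. It was 4.05, 4.59 and 4.50 in knockout spleen and 4.69, 4.70 and 4.26 in knockout bone marrow, so the genotype labels fitted the signal in all 12 arrays. Mir142 fell by 2.91 ± 0.29 in spleen and 2.72 ± 0.32 in bone marrow (limma, Benjamini-Hochberg adjusted p = 7.3e-05 and 0.0003, n = 3 arrays per group). The knockout signals lay near the lower quartile of their arrays, 4.61 to 4.65, where log2 differences are compressed.

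Arrays of 1 group correlated across genes at 0.968 to 0.986, and arrays of different groups at 0.928 to 0.979. The first principal component, with 39.6% of the variance, separated the genotypes, and the second, with 22.0%, separated the tissues. Of the sex-linked list 3 Y-linked genes were measured, and none passed in limma. Eif2s3y stood at -0.41 ± 0.14 in spleen (adjusted p = 0.094, lower adjusted over the list alone) and -0.07 ± 0.15 in bone marrow, Kdm5d at -0.23 ± 0.15 and -0.15 ± 0.17, and Uty at -0.02 ± 0.18 and -0.13 ± 0.20.

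The first comparison asked which genes differed between knockout and wild type NK cells of the spleen. The largest rises were in Plac8 (4.80 ± 0.25), the granzyme gene Gzmc (4.48 ± 0.34), Tspoap1 (4.05 ± 0.17) and the lipid phosphatase gene Inpp4b (3.91 ± 0.19). Tmem273 (3.72 ± 0.29), the cytochrome c oxidase subunit Cox6a2 (3.65 ± 0.18), the integrin CD49a gene Itga1 (3.38 ± 0.22), Tmem176a (3.14 ± 0.20), Gpr34 (3.09 ± 0.21) and Tmsb15a (3.09 ± 0.17) followed. Besides Mir142, the largest falls were in the sialic acid hydroxylase Cmah (-3.32 ± 0.29), Serpinb9b (-2.55 ± 0.21), the plexin Plxnc1 (-2.55 ± 0.24) and the SLAM family receptor Slamf6 (-2.50 ± 0.11). Sidt1 (-2.43 ± 0.12), the diacylglycerol kinase Dgka (-2.24 ± 0.13), the kinase Sgk1 (-2.23 ± 0.31), the chymase Cma1 (-2.21 ± 0.23) and Angpt1 (-2.18 ± 0.32) were next. The Benjamini-Hochberg adjusted p of these genes in limma was at most 0.0012, with n = 3 arrays per group.

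In all, 1090 of 11963 genes passed in spleen, 656 higher and 434 lower in knockout, and 251 of them changed over 2-fold (169 higher, 82 lower). In 1078 of the 1090 the 3 arrays of each genotype did not overlap. That held for 28.0% of all genes, where chance gives 10%. Within each run of array numbers all 1090 genes kept the sign of the pooled difference. The same arrays chose these genes, so that is no independent test. The count was 546 without wild type spleen 3 and 647 without knockout spleen 3. Each of these was the only array of its group in its run.

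**Figure D1:**
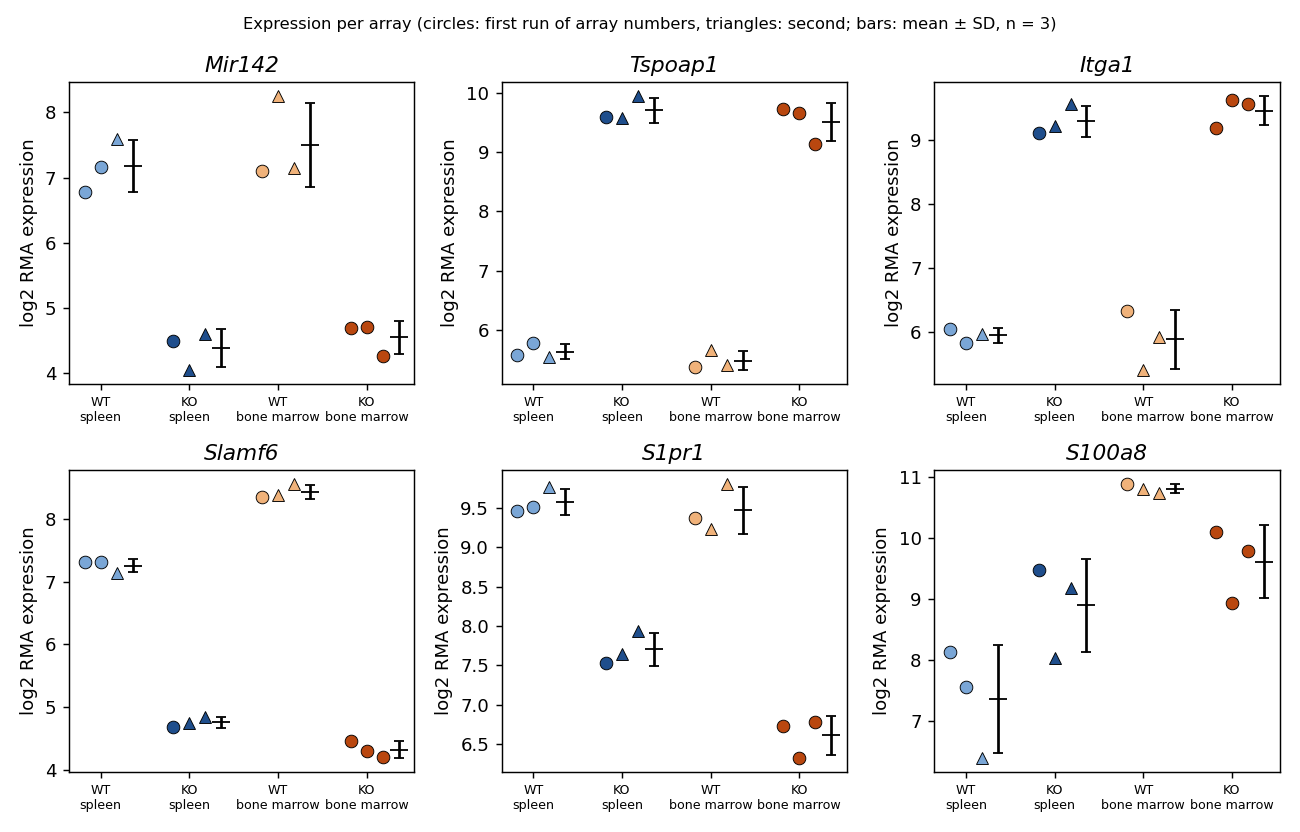
Log2 signal of 6 genes in each of the 12 arrays by group, with circles for the first and triangles for the second run of array numbers and bars for the mean ± SD (n = 3). Mir142 lies between 4.05 and 4.70 in the knockout arrays and at 6.77 or above in the wild type arrays, and Tspoap1 and Itga1 are higher in knockout in both tissues.

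Genes that mark type 1 innate lymphoid cells (ILC1) and tissue-resident lymphocytes rose together in knockout spleen. Of 18 measured members 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.26. The test of limma's camera gave an adjusted p = 5.28e-19, and adjusted p = 0.0116 with an estimated correlation. Itga1, Inpp4b, Gpr34 and Tmem176a had the largest differences. The median was 1.28 within the first and 1.29 within the second run.

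Of the cytotoxic effectors and cytokines, 5 of 20 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 3.15e-05 by camera, adjusted p = 0.0334 with an estimated correlation). Gzmc, the death ligand Tnfsf10 (1.97 ± 0.16), which is also in the ILC1 list, Gzmk (1.74 ± 0.15) and Gzmb (1.14 ± 0.12) were among the genes that rose, and the interferon gamma gene Ifng fell by 1.35 ± 0.30 (limma, adjusted p = 0.014). Prf1 differed by 0.17 ± 0.13 and did not pass. Migration receptors and adhesion molecules went the other way, with 12 of 18 lower and 3 higher (13 and 3 adjusted over the list alone) and a median of -0.66. Camera gave an adjusted p = 3.81e-06, and adjusted p = 0.021 with an estimated correlation. The chemokine receptor Cxcr3 fell by 2.17 ± 0.24, the sphingosine-1-phosphate receptor S1pr1 by 1.95 ± 0.17 and Cd44 by 1.44 ± 0.12, while Cxcr6, also in the ILC1 list, rose by 1.61 ± 0.17.

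Of the reported miR-142 targets, 6 of 19 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.00152, adjusted p = 0.142 with an estimated correlation). They included Il6st (0.96 ± 0.22), Twf1 (0.85 ± 0.10), Itgav (0.77 ± 0.13) and Tgfbr1 (0.42 ± 0.11), and Socs1 differed by 0.15 ± 0.16 and did not pass. In the transforming growth factor beta pathway 5 of 17 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0361, adjusted p = 0.194 with an estimated correlation). Acvr2a (1.11 ± 0.14) led, Itgav and Tgfbr1 are in both lists, and Tgfbr2 differed by 0.17 ± 0.14.

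Genes high in immature NK cells had 6 of 15 lower and 2 higher (camera adjusted p = 0.00203, adjusted p = 0.222 with an estimated correlation), among them Ctla2b (-1.50 ± 0.15) and Kit (-1.39 ± 0.15). Genes high in mature NK cells were divided, with 4 of 13 lower and 2 higher (camera adjusted p = 0.0492, adjusted p = 0.544 with an estimated correlation; lost in 11 of 27 alternatives). Cma1 and Cx3cr1 (-1.06 ± 0.21) fell, and Gzmb and the receptor Klrg1 (1.13 ± 0.25) rose. The transcription factors Eomes (-0.11 ± 0.10) and Tbx21 (-0.05 ± 0.15), and Itgam, Cd27, Bcl2, Mcl1 and Il2rb, did not pass.

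Markers of other cell types moved as well. Of 11 dendritic cell markers 6 rose and 0 fell (camera adjusted p = 0.000248, adjusted p = 0.142 with an estimated correlation), including the MHC class II genes H2-Aa (2.00 ± 0.33) and H2-Ab1 (1.66 ± 0.20) and the integrin Itgax (1.36 ± 0.11). Of 11 granulocyte markers 1 rose (3 adjusted over the list alone), S100a8 by 1.81 ± 0.37 (camera adjusted p = 0.0137, adjusted p = 0.469 with an estimated correlation). The dendritic cell markers Siglech, Flt3, Xcr1, Clec9a and Cd209a lay below the filter and were not tested. So did the granulocyte markers Ltf, Mmp8, Mmp9, Ly6g, Ctsg, Ms4a3 and Chil3. Whether these calls reflect other cells in the sorted samples was not settled by the lists. In all, 9 of 27 lists passed with the preset and 3 with the estimated correlation. For 8 lists, none of them called, the signs of the median, the mean and the test were not all the same.

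In bone marrow the same question gave Gsta4, a glutathione transferase gene (4.45 ± 0.28), Tmem273 (4.27 ± 0.32), the semaphorin Sema6d (4.19 ± 0.25), and Tspoap1 (4.07 ± 0.19) as the largest rises, followed by Gzmc (adjusted p = 6.6e-05). Itga1 (3.49 ± 0.24), Gpr34 (3.41 ± 0.23), the Ly49 family receptor Klra5 (2.96 ± 0.29), the E-cadherin gene Cdh1 (2.93 ± 0.21) and Mab21l2 (2.91 ± 0.19) were next. Slamf6 (-4.09 ± 0.13), the NKG2D ligand H60b (-3.62 ± 0.40), Dgka (-3.48 ± 0.14), Cd3d (-3.14 ± 0.26) and Cmah (-3.08 ± 0.32) fell most, and then Cxcr3 (-2.94 ± 0.27), Klf3 (-2.90 ± 0.19), Sidt1 (-2.80 ± 0.14) and S1pr1 (-2.71 ± 0.19). Their Benjamini-Hochberg adjusted p in limma was at most 0.00018 (n = 3 arrays per group).

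In bone marrow 1035 genes passed, 469 higher and 566 lower, with 291 over 2-fold (166 higher, 125 lower). The arrays of the genotypes did not overlap in 1019 of them, against 34.2% of all genes and 10% by chance. All 1035 kept their sign within the first run, where wild type bone marrow 1 was the only wild type bone marrow array, and the second run held no knockout bone marrow array. Here too the genes were chosen from the same arrays, so the signs are no independent test. The count was 371 without wild type bone marrow 1 and, in alternatives chosen after seeing the data, 218 without wild type bone marrow 1 and 2 and 92 with granulocyte marker level as a covariate. Quantile normalization applied again gave 539 higher and 379 lower.

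The ILC1 and residency list rose in bone marrow too, with 13 of 18 higher and 0 lower (15 and 1 adjusted over the list alone) and a median of 1.41 (camera adjusted p = 4.56e-15, adjusted p = 0.0232 with an estimated correlation). Within the first run its median was 1.27. Of the migration list 8 of 18 fell and 2 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.000448, adjusted p = 0.0813 with an estimated correlation), with Cxcr3, S1pr1 and Cd44 (-1.79 ± 0.13) lower and Cxcr6 (1.89 ± 0.19) higher. Of the cytotoxic list 5 of 20 rose and 3 fell (camera adjusted p = 0.0238, adjusted p = 0.211 with an estimated correlation). Tnfsf10 (2.27 ± 0.18) and Gzmb (1.31 ± 0.14) were higher, and Ifng was lower by -2.08 ± 0.33. The miR-142 targets had 3 of 19 higher and 1 lower (camera adjusted p = 0.0467, adjusted p = 0.32 with an estimated correlation; lost in 12 of 27 alternatives), with Cfl2 (1.25 ± 0.13), Itgav (0.55 ± 0.15) and Twf1 (0.53 ± 0.12) higher and Smad3 (-0.54 ± 0.14) lower. In the transforming growth factor beta list 6 of 17 rose and 2 fell (camera adjusted p = 0.00342, adjusted p = 0.134 with an estimated correlation). Of the genes high in immature cells 5 of 15 fell, including Kit (-1.31 ± 0.17) (camera adjusted p = 0.00626, adjusted p = 0.283 with an estimated correlation). The list high in mature cells did not pass (adjusted p = 0.161), although Klrg1 rose by 1.38 ± 0.27 and Cma1 fell by 1.75 ± 0.26. Eomes (0.04 ± 0.11), Tbx21 (-0.12 ± 0.17), Tgfbr1 (0.31 ± 0.12) and Itgam (-0.61 ± 0.18) did not pass.

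Granulocyte markers were lower in knockout bone marrow, with 4 of 11 lower and 0 higher (6 and 0 adjusted over the list alone) and a median of -1.12 (camera adjusted p = 0.000359, adjusted p = 0.233 with an estimated correlation). Retnlg (-1.94 ± 0.32), S100a8 (-1.74 ± 0.41) and Lcn2 (-1.72 ± 0.28) were among them. Beside them, 4 of 32 cell cycle genes were lower, the DNA replication helicase genes Mcm4 (-1.11 ± 0.24), Mcm3, Mcm7 and Mcm5 (median of the list -0.68, camera adjusted p = 0.000348, adjusted p = 0.553 with an estimated correlation). The list stood at 1.21, 0.40 and -0.47 in the 3 knockout bone marrow arrays, and its call was lost without wild type bone marrow 1 or knockout bone marrow 3, and with fry. In spleen the cell cycle list was not called in the main fit, and 10 of 27 alternatives called it. The direction of those spleen calls is not given here, and they need not be a fall. The bone marrow effect minus the spleen effect had a list median of -0.94, lower than the bone marrow median. Of 10 T cell markers 4 fell, Cd3d, Cd3g (-1.69 ± 0.24), Cd28 (-1.28 ± 0.16) and Cd3e (camera adjusted p = 0.00313, adjusted p = 0.171 with an estimated correlation). Immediate early genes had 3 of 23 lower and 1 higher, with Nr4a1 at -1.89 ± 0.44 (camera adjusted p = 0.0159, adjusted p = 0.553 with an estimated correlation; lost in 9 of 27 alternatives). Dendritic cell markers had 2 of 11 higher, Itgax (1.46 ± 0.12) and Tcf4 (camera adjusted p = 0.000448, adjusted p = 0.171 with an estimated correlation). With the preset correlation 11 lists passed, and 1 with the estimated.

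**Figure D2:**
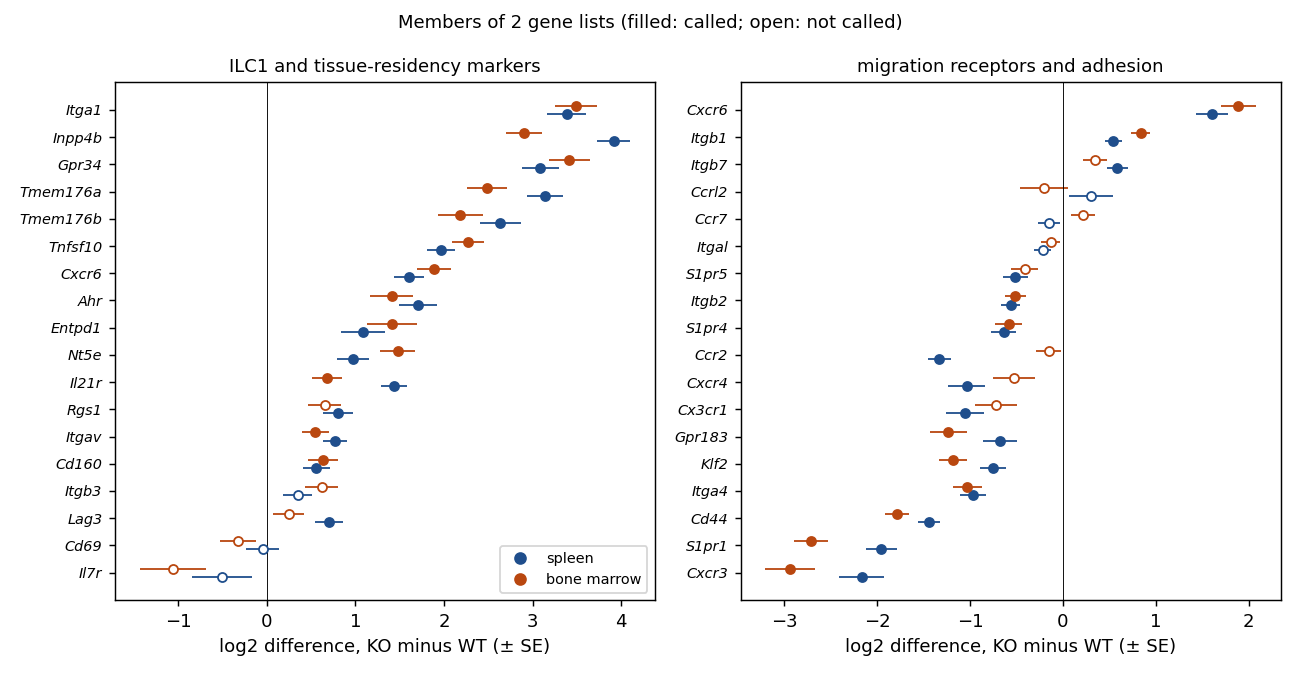
Knockout minus wild type log2 difference ± SE of each measured member of the ILC1 and residency list and of the migration list, by tissue (n = 3 arrays per group), with filled points for genes that passed. Of the ILC1 list 15 of 18 members rose in spleen and 13 in bone marrow, and of the migration list 12 of 18 fell in spleen and 8 in bone marrow.

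Over both tissues 2290 genes passed, 1054 higher and 1236 lower in knockout, and 243 changed over 2-fold (164 higher, 79 lower). Gzmc (4.24 ± 0.24), Tspoap1 (4.06 ± 0.12), Tmem273, Gsta4 (3.62 ± 0.18) and Plac8 (3.47 ± 0.17) had the largest rises, and Slamf6 (-3.30 ± 0.08), Cmah (-3.20 ± 0.20), H60b (-2.88 ± 0.25) and Dgka (-2.86 ± 0.09) the largest falls (limma, adjusted p at most 9.3e-06). Il2rb (0.22 ± 0.07), Tgfbr1 (0.36 ± 0.07) and Itgam (-0.44 ± 0.11) passed here. Eomes stood at -0.03 ± 0.07, with a 95% interval from -0.19 to 0.12. Quantile normalization applied again gave 1233 higher and 1013 lower, and median centring moved the balance the other way, to 922 higher and 1476 lower.

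The ILC1 list had 16 of 18 members higher and 1, Il7r, lower over both tissues (adjusted p = 0.0165 with an estimated correlation), and the migration list 12 of 18 lower and 3 higher (adjusted p = 0.0324 with an estimated correlation). Cytotoxic genes had 8 of 20 higher and 2 lower, the miR-142 targets 7 of 19 higher and 1 lower, the transforming growth factor beta list 8 of 17 higher and 2 lower, and dendritic cell markers 7 of 11 higher, all called by camera with the preset correlation only. Genes high in immature NK cells had 8 of 15 lower and 2 higher (camera adjusted p = 0.00329, adjusted p = 0.226 with an estimated correlation), and those high in mature cells 5 of 13 lower and 2 higher (camera adjusted p = 0.0355, adjusted p = 0.571 with an estimated correlation), a call lost in 8 of 26 alternatives. Of the NK receptor list 9 of 24 rose and 5 fell (camera adjusted p = 0.687), with Styk1 and Tigit (1.01 ± 0.09) higher. In the IL-15 and JAK-STAT list 5 of 21 rose and 6 fell (camera adjusted p = 0.687), with Cish (1.56 ± 0.17) higher and Il18rap (-0.97 ± 0.08) lower. Klra5 (2.73 ± 0.18), Klra3 and Klra8 rose among 4 measured Ly49 receptors, a family with similar sequences. Actin regulators had 4 of 21 higher and 5 lower, apoptosis genes 3 of 17 higher and 1 lower, glycolysis genes 2 of 14 higher and 3 lower, and interferon-stimulated genes 3 of 19 higher and 1 lower, and none of these lists passed camera, while fry called glycolysis (adjusted p = 0.0364). Dstn (1.32 ± 0.14), Bcl2l11 (0.69 ± 0.09), Pfkp (-0.86 ± 0.08) and Ifih1 (0.68 ± 0.11) led them. None of 20 ribosomal protein genes passed in limma, and 1 of 11 small RNA pathway genes did, Drosha (-0.42 ± 0.10).

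Of 10 T cell markers 4 fell over both tissues, Cd3d, Cd3g, Cd28 and Icos (camera adjusted p = 0.0224, adjusted p = 0.226 with an estimated correlation). Among the other cell types, 1 of 7 B cell genes (Cd72, -0.43 ± 0.10) and 1 of 5 monocyte genes (Ms4a6c, -0.84 ± 0.12) fell over both tissues, 1 of 8 erythroid genes rose and 1 fell, and 1 of 6 plasma cell genes rose (Igha, 0.49 ± 0.13). Of 6 platelet genes 1 fell (F2rl2, -0.80 ± 0.14), and of 5 markers of other innate lymphoid cells Rora (0.54 ± 0.10) rose and Icos (-0.46 ± 0.09) fell. Progenitor markers had Hoxa9 (1.60 ± 0.10) and Meis1 (1.23 ± 0.17) higher and Kit and Myb lower among 9. The 2 measured basophil and mast cell markers, Gata2 (0.04 ± 0.08) and Prss34 (-0.07 ± 0.24), did not pass. For Ighm, 3 probe sets ranged from -0.03 to 1.98 in spleen. The 2 probe sets of Igha stood at 0.005 and 0.26 in spleen and 0.46 and 0.72 in bone marrow, and the one used had the higher value in both.

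Tspoap1 is the nearest protein-coding gene on 1 side of Mir142 in assembly GRCm38.p6. On the other side lie Supt4a, which had no probe set of its own here, and then Rnf43, which fell by 1.32 ± 0.14 in spleen and 1.21 ± 0.16 in bone marrow. Farther out Septin4 fell by 0.55 ± 0.13 and 0.80 ± 0.15, and Mpo, Mtmr4 and Mks1 did not pass (limma). Of 85 tested genes within 5 Mb of Mir142, 5 rose and 9 fell over both tissues.

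The tissues were then compared with each other. Of the called genes 313 were higher in knockout in both tissues, 240 lower in both and 5 opposite, where independent lists would share 25.7 and 20.5. Across genes, which are not independent replicates, the differences correlated at r = 0.63 (rho = 0.40) with a covariance of 0.0921. Unchanged groups simulated in the same model gave an r of -0.14 and a covariance of -0.00377. With each tissue fitted alone, without the run covariate, r was 0.70.

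**Figure D3:**
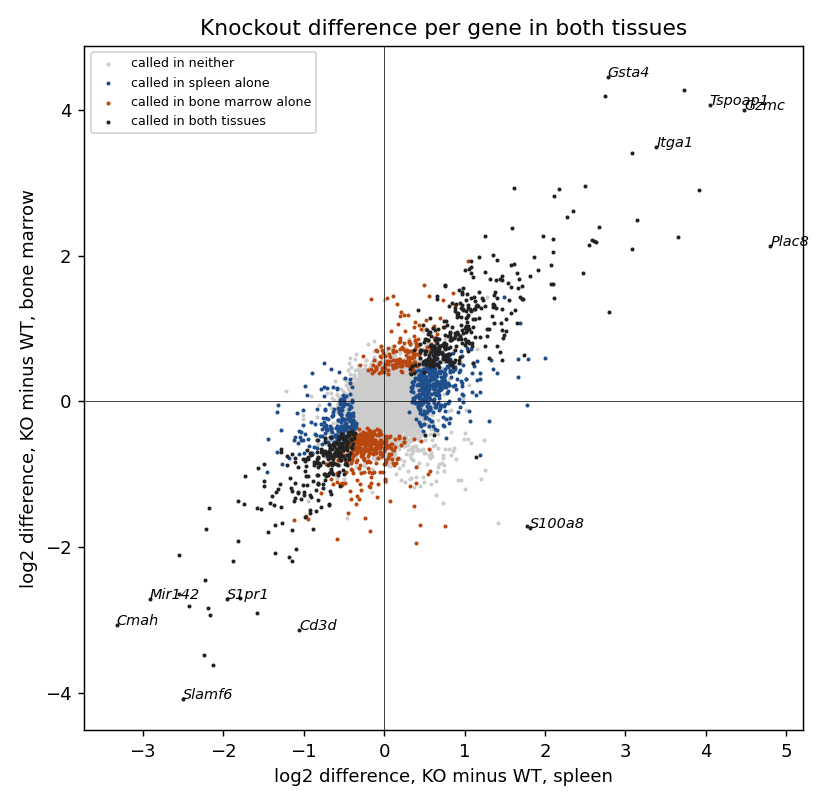
Knockout minus wild type log2 difference in spleen (x axis) and bone marrow (y axis) for each tested gene, coloured by where it was called. Of the genes called in both tissues 313 lie in the upper right, 240 in the lower left and 5 in the other corners.

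The test of the difference between the knockout effects in bone marrow and spleen called 1 gene in limma, with 1092 at an unadjusted p under 0.05. Slamf6 fell further in bone marrow, by -1.59 ± 0.18 (adjusted p = 0.019). Its mean was 7.25 in wild type spleen, 8.43 in wild type bone marrow, 4.76 in knockout spleen and 4.32 in knockout bone marrow, and both knockout means lay below the filter level of 5.49. The next smallest p belonged to Car1 (-3.48 ± 0.48, adjusted p = 0.071), Slc7a5 (-1.91 ± 0.28), Plac8 (-2.67 ± 0.40) and Lair1 (-1.10 ± 0.17, adjusted p = 0.075), which did not pass. Of the lists, 6 passed camera, all towards a lower effect in bone marrow, and 0 with an estimated correlation, 3 without knockout spleen 3 and 3 without the run covariate. They were cell cycle genes (median -0.94, adjusted p = 4.97e-09, adjusted p = 0.517 with an estimated correlation), granulocyte markers (-1.52, adjusted p = 4.97e-09, adjusted p = 0.136 with an estimated correlation), immediate early genes (-0.64), glycolysis (-0.21), T cell markers (-0.20) and erythroid markers (-0.28). No member of them passed on its own over all genes, S100a8 standing at -3.54 ± 0.59 (adjusted p = 0.084), and 6 granulocyte, 3 T cell and 2 erythroid markers were lower adjusted over the list alone. The difference for Itga1 was 0.11 ± 0.34 and for Eomes 0.15 ± 0.16. The count was 0 without wild type bone marrow 1 and 5 without knockout bone marrow 1.

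Bone marrow and spleen NK cells were compared within each genotype to see which genes differed by tissue. In wild type cells S100a8 (3.72 ± 0.37), S100a9 (3.31 ± 0.47), Plac8 (2.95 ± 0.25), Ngp (2.83 ± 0.53) and Lcn2 (2.55 ± 0.26) were higher in bone marrow, and all but Plac8 are in the granulocyte list. The mitotic genes Kif11 (2.82 ± 0.57), Ccnb2 (2.65 ± 0.55), Bub1 (2.59 ± 0.64), Ccna2 (2.59 ± 0.50) and Cdca8 (2.49 ± 0.46) were higher there too. Mir103-2 (-1.50 ± 0.31), Klrg1 (-1.48 ± 0.25), the transcription factor Zeb2 (-1.40 ± 0.16), Cma1 (-1.26 ± 0.23), S1pr5 (-1.23 ± 0.13), Cx3cr1 (-1.10 ± 0.21) and Itgam (-1.07 ± 0.17) were lower (limma, adjusted p at most 0.038, n = 3 arrays per group). Prf1 (-0.64 ± 0.13) and Kit (-0.90 ± 0.15) were lower and Bcl2 (0.55 ± 0.14) higher.

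In wild type 643 genes passed, 519 higher and 124 lower in bone marrow, with 150 and 11 over 2-fold. Of the cell cycle list 22 of 32 genes were higher and 0 lower (29 and 0 adjusted over the list alone), with a median of 1.53 (camera adjusted p = 1.15e-20, adjusted p = 0.232 with an estimated correlation). Beside them 7 of 11 granulocyte markers were higher, with a median of 1.59 (camera adjusted p = 1.34e-08, adjusted p = 0.119 with an estimated correlation), as were Cd3d (1.88 ± 0.23), Cd3e and Cd3g among 10 T cell markers. Of the genes high in mature NK cells 6 of 13 were lower and 0 higher (camera adjusted p = 9.44e-09, adjusted p = 0.119 with an estimated correlation), and 5 of 14 glycolysis genes were higher (camera adjusted p = 0.000153, adjusted p = 0.0751 with an estimated correlation). The ribosomal (1 of 20 higher), immediate early (1 of 23), erythroid (2 of 8) and ILC1 lists (4 of 18 higher, 1 lower) also passed camera upward and NK receptors (2 of 24 higher, 3 lower) downward, and 0 lists passed with an estimated correlation. The ILC1 call was lost in 13 of 26 alternatives and that of the NK receptors in 7. The count of genes was 82 without wild type bone marrow 1 and 147 without wild type spleen 3, and 0 with granulocyte marker level as a covariate, an alternative chosen after seeing the data. Quantile normalization applied again gave 419 higher and 179 lower.

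**Figure D4:**
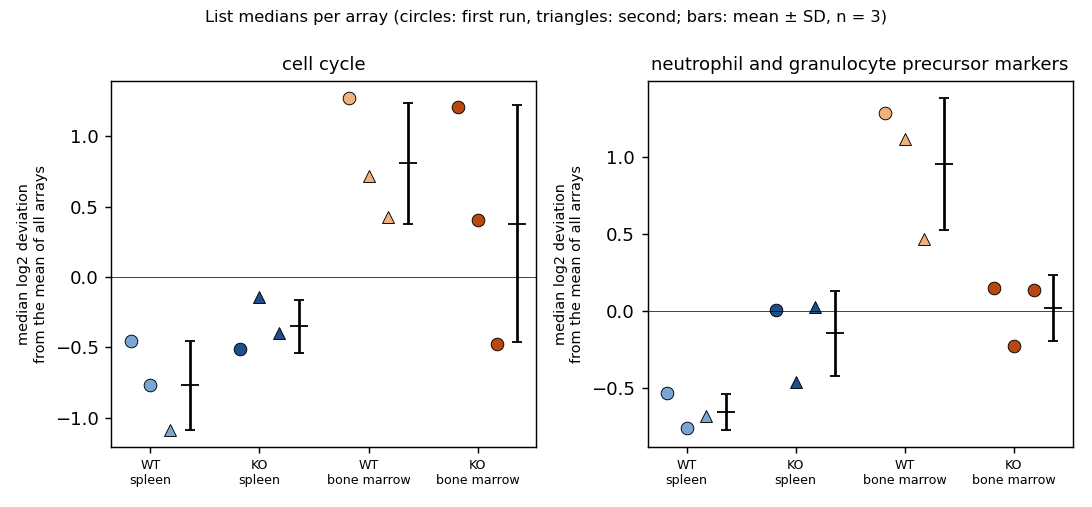
Median log2 deviation from the mean of all arrays over the cell cycle list and the granulocyte list, 1 point per array by group, with circles for the first and triangles for the second run and bars for the mean ± SD (n = 3). The granulocyte median is 0.47 to 1.28 in wild type bone marrow and 0.15 or lower in the other groups, and the cell cycle median ranges from -0.47 to 1.21 in knockout bone marrow.

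In knockout cells 38 genes differed between the tissues, 11 higher and 27 lower in bone marrow. Gpx8 (-2.43 ± 0.27), Klf3 (-2.27 ± 0.19), As3mt (-1.75 ± 0.17), Parm1 (-1.69 ± 0.24), Borcs7 (-1.60 ± 0.21), the inhibitory Fc receptor Fcgr2b (-1.43 ± 0.15) and Itgam (-1.42 ± 0.18) were lower, and Gsta4 (1.72 ± 0.28), the chemokine receptor Ccr2 (1.41 ± 0.14), Cass4 (1.38 ± 0.23) and Capg (1.28 ± 0.16) higher (limma, adjusted p at most 0.032). Of the list high in mature NK cells 2 of 13 were lower, Itgam and S1pr5 (-1.13 ± 0.15), and 8 adjusted over the list alone (camera adjusted p = 3.85e-11, adjusted p = 0.116 with an estimated correlation). None of the 32 cell cycle genes passed in limma (median 0.54, camera adjusted p = 9.98e-07, adjusted p = 0.593 with an estimated correlation), and the call of that list was lost without knockout spleen 3 or knockout bone marrow 1. Camera also called lower cytotoxic (0 of 20 genes passing), migration (1 of 18 higher, 1 lower), NK receptor (1 of 24 lower) and miR-142 target lists (0 of 19), and higher immature NK cell (1 of 15 higher) and ribosomal lists (0 of 20), 0 of them with an estimated correlation. Of 26 alternatives, 21 lost the call of the miR-142 targets, 16 that of the ribosomal list and 8 that of the NK receptors. Median, mean and test differed in sign for 2 lists in the bone marrow comparison, 7 over both tissues, 4 in the interaction, 4 between tissues in wild type and 5 in knockout, none of them called. The count of genes was 1 without knockout spleen 3, and 1106 genes had an unadjusted p under 0.05. Knockout spleen 3 was the only knockout spleen array of the first run, which held all knockout bone marrow arrays.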

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

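The tests of the 2 runs, of Eomes, of granulocyte RNA and of a wide segment around Mir142, and the list tests of the difference between tissues, were chosen after the result was seen. The knockout effect differed between tissues for 1 gene and 6 lists in a test of the difference itself. Slamf6 changed by -1.59 more in bone marrow, with both knockout means below the filter level, where differences are compressed. The lists, as median differences of the effect, were cell cycle (-0.94), immediate early genes (-0.64), glycolysis (-0.21), T cell markers (-0.20), granulocyte markers (-1.52) and erythroid markers (-0.28), and 0 of them passed with an estimated correlation, 3 without knockout spleen 3 and 1 without wild type bone marrow 1 and 2. The gene comparisons left out the probe sets without a single gene symbol. Of those, 7112 were tested apart, and 160 were called over both tissues (87 higher and 73 lower in knockout).

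Other splits of the arrays were counted for each result. Over both tissues 1 of 100 splits called as many genes as the real one, the real one itself, with 2290 genes against at most 165 in the others, so a chance split can be excluded there. For the difference between tissues 11 of 100 splits called as many as the real 1 gene, up to 165. The splits with 165 and 160 genes keep the spleen genotypes whole, so they carry the genotype difference, which is a structure of the samples. Such splits do not show what chance alone gives, so this count cannot decide whether the 1 gene came from chance. For the number of lists over both tissues 9 of 100 splits gave 9 or more, up to 12, so chance cannot be excluded for that count. The same 100 splits include ones that keep the genotypes of a tissue whole, so this share does not measure chance alone. The split with 165 genes over both tissues is also of that kind. Within 1 tissue or genotype there are 10 splits, too few for a share under 0.05. Of these 1 called as many genes in spleen (1090, highest other 0), in bone marrow (1035, highest other 0), between tissues in wild type (643, highest other 0) and in knockout (38, highest other 1). The same held for lists in spleen (9, highest other 7) and bone marrow (11, highest other 7), with 1 split each.

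Tspoap1 and Rnf43, the nearest measured genes on either side of Mir142, changed over 2-fold in opposite directions. Among tested genes, 0.115% had nearest neighbours on both sides that changed over 2-fold, in whichever direction, which is consistent with a change local to the altered locus as a hypothesis. A segment of another strain several megabases wide with 2 times the usual share of changed genes is argued against by a share of 16.5% within 5 Mb (95% limits 9.31% to 26.1%) beside 19.2% elsewhere. A short segment, a wide one with a smaller excess of changed genes, or an effect of the altered allele on its neighbours stays open. A response of Tspoap1 to the loss of miR-142 itself was not tested.

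Of 11 granulocyte markers 7 were higher in wild type bone marrow than in wild type spleen and 4 higher than in knockout bone marrow, and the list passed with the preset correlation only (adjusted p = 0.119 and 0.233 with an estimated correlation). S100a9 stood at 10.98 in wild type bone marrow, 9.93 in knockout bone marrow, 9.08 in knockout spleen and 7.98 in wild type spleen, and S100a8 at 10.81, 9.61, 8.90 and 7.36, while Cebpe and Fcnb were not higher. RNA of granulocytes in these samples, which the CD3-negative NK1.1-positive gate would remove, stays open, since of 24 other granulocyte genes named afterwards only 8 could be tested, of which 5 were higher in bone marrow and only Alox5ap passed, their median at the 89.8th percentile of random lists of like level. As the whole cause of the bone marrow calls it is argued against, since 91.6% of those genes moved the same way in spleen, where the granulocyte markers did not fall. A biological difference between the tissues stays open and was not tested, as does the part of the bone marrow calls that granulocyte RNA could account for.

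ILC1 and residency markers were higher in knockout in both tissues. The 2 runs of arrays are argued against as the cause, since the smallest median difference within a run was 1.27. That value compares 3 knockout arrays with 1 wild type array in bone marrow of the first run. In spleen the first run held 2 wild type arrays and 1 knockout array, and the second 1 wild type array and 2 knockout arrays. Each within-run difference thus rests on a single array of 1 genotype, and the second run held no knockout bone marrow array. A larger share of Eomes-negative cells in the knockout gate may contribute, and Eomes differed by -0.0321 (95% limits -0.19 to 0.12), which leaves a small shift in cell shares open. Whether the genes rose within each cell or the mixture of cells changed cannot be told apart from sorted pools, since each array averages over cells.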

How the results depend on the processing

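The granulocyte marker covariate and the fit without wild type bone marrow 1 and 2 were chosen after seeing the data. Of the named genes called, 49 of 75 in spleen, 50 of 83 in bone marrow, 80 of 98 over both tissues, 0 of 1 in the interaction, 15 of 61 between tissues in wild type and 1 of 22 in knockout passed under every alternative fixed before the data were seen, the 60th percentile filter left aside. Where no reason is given, the cause was not tested. The planned miR-142 site tests were not run, for want of 3' untranslated region sequence. Genes near the floor, such as Slamf6 and Mir142 in knockout, have compressed differences.

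Without the run covariate bone marrow had 1590 genes, the interaction 2, with 3 lists in place of 6, and tissue in knockout 87. The 60th percentile filter, which drops Slamf6, left 0 in the interaction, the trend and robust model gave 3, and array weights 2, with 1135 for tissue in wild type. With an estimated correlation 3, 1 and 2 lists passed in spleen, bone marrow and both. Median centring gave 372 higher and 850 lower in bone marrow and 764 and 85 for tissue in wild type.

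With the replicate number as a block beside the run the interaction had 5 genes. With the block and no run covariate bone marrow had 1662, the interaction 11 and tissue in knockout 128, and the lists of the interaction went from 6 to 3. No other count moved by over 1.5 times under the block. The deviations of arrays with the same number correlated at -0.01 to 0.09 between genotypes in spleen, -0.02 to 0.24 in bone marrow, 0.04 to 0.13 between tissues in wild type and 0.04 to 0.20 in knockout. Each array correlated best with its own number in 2, 2, 3 and 3 of 3 pairs, a hint from the data. The labels name no pairing and not every pair of any 2 groups was over 0.1, so none was assumed. After the run covariate the ranges were 0.112 to 0.535, -0.04 to 0.24, -0.11 to 0.11 and 0.03 to 0.28. Unpaired arrays would give 0.0909 to 0.5, 0, -0.21 to 0.09 and 0, and every value between tissues was higher. Shared mice across tissues thus stay open, and the main fit ignores them.

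Without wild type bone marrow 1 and 2, the arrays highest in granulocyte markers, bone marrow had 218 genes and 6 lists, both tissues 1346, the interaction 0 and 1 list, tissue in wild type 1 and tissue in knockout 16, with fewer arrays as part of the cause. The granulocyte covariate, which follows the groups and so takes part of their difference, left 360 in spleen, 92 and 2 lists in bone marrow, 0 and 2 lists in the interaction, and 0 and 4 lists for tissue in wild type. It turned Camp to 0.21 and S100a8 to 0.15 in knockout bone marrow, and Ngp to -1.94, S100a9 to -0.21 and Slamf7 to 0.15 between tissues in wild type. All but Slamf7 belong to the granulocyte list, whose mean was the covariate, so their turned signs are no separate evidence.

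Leaving out each array in turn gave 546 to 1083 genes in spleen (546 without wild type spleen 3, 647 without knockout spleen 3), 371 to 1006 in bone marrow (371 without wild type bone marrow 1), 1675 to 2178 over both and 0 to 5 in the interaction (5 without knockout bone marrow 1, 3 without wild type spleen 1, 2 without knockout bone marrow 2 or knockout spleen 1 or 2, 0 without wild type bone marrow 1 or 2, knockout bone marrow 3 or wild type spleen 3). Slamf6 lost its call in the interaction without wild type spleen 3, wild type bone marrow 1 or 2, or knockout spleen or bone marrow 3. Tissue in wild type gave 82 to 702 (82 without wild type bone marrow 1 and 395 without 2; 323, 294 and 147 without wild type spleen 1, 2 and 3). Tissue in knockout gave 1 to 38 (1 without knockout spleen 3, 20 without knockout spleen 1, 22 without knockout bone marrow 3, 21 without wild type spleen 3, 25 without wild type bone marrow 1 or 2). Lists ranged over 6 to 10 in spleen, 8 to 11 in bone marrow and 8 to 10 over both. In the interaction they were 3 without knockout spleen 3 and otherwise 6 or 7, between tissues in wild type 9 or 10, and in knockout 4 without knockout spleen 3, 5 without wild type spleen 2 and otherwise 6 to 9. Besides the tallies given beside lists, the spleen calls of the transforming growth factor beta list and of granulocyte markers were lost in 5 of 27 and 5 of 26 alternatives, and the bone marrow call of the cytotoxic list in 4 of 27. Some lists gained a call, most often the cell cycle list in spleen, in 10 of 27 alternatives. Migration receptors gained one between tissues in wild type in 7 of 26, and immediate early genes between tissues in knockout in 6 of 26. With fry 3 lists passed in the interaction and 3 between tissues in knockout.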

Other observations

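The test of segments of another strain was written down before its result was seen, and how its value is read was changed afterwards, as stated beside it. Several genes outside the comparisons' lists changed in knockout cells and were chosen after their values were seen. In a stretch of chromosome 1 of assembly GRCm38.p6, the interferon-inducible genes Ifi208 (-2.03 ± 0.29), Ifi214 (-1.22 ± 0.21), Ifi213 (-1.19 ± 0.18) and Ifi206 (-1.12 ± 0.13) and the Fc receptor Fcgr2b (-1.05 ± 0.10) were lower over both tissues. Aim2 (1.14 ± 0.10), a DNA sensor of the same family, and Cfap126 (1.35 ± 0.14) were higher, and Slamf6 (-3.30 ± 0.08) lies in the same stretch (limma, Benjamini-Hochberg adjusted p at most 0.0014, n = 3 arrays per group and tissue). Members of the Ifi200 family have similar sequences.

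A hypothesis was that genes changed over 2-fold lie together, as segments of another strain elsewhere in the genome could leave them. Of 142 stretches of 20 Mb, 0 held more such genes than chance at an adjusted p under 0.05. The leading stretch, that on chromosome 1, held 8 of 110 tested genes where 2.21 would come from chance (exact hypergeometric test of enrichment, p = 0.00166, Benjamini-Hochberg adjusted p = 0.236). As first written, 0 stretches would have counted against the hypothesis. That reading was dropped after the value was seen, because a count of 0 at a threshold does not exclude short segments. The changed reading also asked whether the share in the leading stretch (7.27%, 95% limits 3.19% to 13.8%) stayed below 2 times the 2.01% of all genes. Its upper limit did not. That stretch was picked for the smallest p of 142, and its limits do not allow for the choice, so they decide nothing. The test thus gives no positive evidence for such segments and does not exclude them.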
